A study of Mus musculus with 7 samples.

How the data were processed

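The data are UMI counts from droplet single-cell RNA sequencing (10x Genomics) of sorted mouse muscle stromal cells in 7 libraries, 6 of a CTX injury course and 1 pool of 5 hashtag groups. The deposited count tables hold raw UMI counts per gene and cell, not normalised, for 25787 genes in the CTX libraries and 28692 in the pool. The authors named Cell Ranger (no version given) and Seurat 4.1.2 for making them, on genome build mm10. The labels and the series text name different chemistries, and no step here depends on which is right. The least number of detected genes in any cell was 501 to 503 in the CTX libraries and 648 in the pool, and no cell had more than 10% mitochondrial UMIs, so the tables had been filtered before they were deposited. The other deposited values are cell lists, in which the authors give each CTX cell its time point and each pool cell its hashtag, and all 57881 listed cells were used. How hashtags were assigned is not stated, nor is the number of animals behind a library or hashtag.

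Counts were summed over the cells of each group and divided by the group's total. Ratios are log2 with a pseudocount of 1 CPM, and folds are given without it. Each fold has an exact conditional (Clopper-Pearson) 95% interval, which covers counting error only, as do the Clopper-Pearson intervals of shares of cells. With 1 library or hashtag per group, no test between groups was run. The 10 comparisons were each CTX day against the uninjured library, Dmdmdx against DBA/2J at 2.5 and at 12.5 weeks, Dmdmdx at 5 and at 12.5 against 2.5 weeks, and DBA/2J at 12.5 against 2.5 weeks. A gene counted as higher or lower when it had at least 20 CPM in either group and differed by at least 2-fold. Where a group had a count of 0, the fold was set against a floor of 3 counts in that library. Gene positions came from GENCODE vM21.

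The comparisons, 19 gene lists, 17 lists of cell type markers, the rule for named genes and most alternatives were set before the data were examined. The gene lists were myeloid recruitment, NF-kB and IL-1 response, immediate early, heat shock, interferon response, class I antigen presentation, provisional matrix, fibrillar matrix, basement membrane, matrix proteases, cell cycle, myofibroblast, complement, adipogenic, stromal growth factors, glycolysis and hypoxia, ribosome biogenesis, unfolded protein response and stromal identity. For each list the median log2 ratio over members with at least 10 CPM in either group was set against 10000 random lists of the same size, matched on expression in 20 bins. Lists overlap in places, so their results are not independent. Named genes were those with at least 50 CPM in either group whose share of cells moved the same way, without predicted, mitochondrial or ribosomal protein genes. The rule took the 10 highest and 10 lowest ratios at days 0.5, 1 and 3, the outermost 6 each way at days 7 and 14, and 8 each way in hashtag comparisons, with up to 4 members of each list, all cell type markers, and Dmd. Lists of imprinted, circadian clock and neutrophil genes were chosen after values had been seen.

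For shares of cells, each cell was thinned at random to 1000 UMIs in the CTX libraries and 3000 in the pool, depths that at least 90% of cells in every group reach, and shallower cells were left out. The spread of a list over cells was the share of its UMIs in the 10% of cells richest in them, beside the share expected if every cell had the same rate. Each library was clustered on its own with 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 0.6, which gave 77 clusters. Cluster names were adjusted after the clusters had been seen, and cluster sizes were not compared between groups. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.

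The steps were tested on simulated data built from the real totals, with 200 genes changed by a known amount. None of the unchanged genes passed 2-fold, all genes planted at 2.5-fold or 4-fold were called, and 94.93% and 95.6% of the intervals held the true value in the pair of comparisons simulated. Of unplanted lists, 4.5% and 2.5% fell outside percentiles 2.5 to 97.5. The simulated groups differed by counting error and the planted changes only, so these results were likely in advance. They do not cover differences between animals or in handling, which cannot be measured without replicates. Whether the list percentiles hold for genes that move together was not tested. Exploratory tables of the comparisons had been looked at before this test was run.

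Alternatives set beforehand were TMM factors, the mean of each cell's CPM, thinned cells, gene minimums of 5 and 100 CPM, a pseudocount of 10 CPM, leaving out non-stromal clusters with called doublets, and leaving out cells over 10% mitochondrial UMIs. For cells, they were unthinned shares, thinning to 0.5 of the depth, another seed, and clustering at resolutions 0.3 and 1 or without cell cycle genes. The first rule for non-stromal clusters asked for at least 3 markers of another type among 30 leading genes and for stromal genes below 0.5 of their level elsewhere, and it took 0 clusters. A looser rule without the level of stromal genes, set after that was seen, took 6 clusters and, in DBA/2J at 12.5 weeks, 1396 of 2342 cells. Clusters it took are called led by other cell types' markers, although some also had stromal markers among their leading genes. The doublet caller, a Scrublet-like score, marked 10 of 57881 cells and is not taken to have worked. Leaving out cells over 5% mitochondrial UMIs, the 5% of cells with the highest doublet scores, and the shallower cells of each group were likewise added later. The CTX and pooled libraries were set side by side only through ratios made within each. Empty droplets, sequence reads and hashtag counts were not used here, and 1 of the marker lists is not reported here.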

Results

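Single-cell RNA sequencing measured the transcripts of mesenchymal stromal cells sorted from mouse hindlimb muscle, called MmSCs in the labels. In the injury course, male C57BL/6 Foxp3-GFP mice of 6 to 8 weeks gave 6 libraries: 1 from uninjured muscle and 1 each from days 0.5, 1, 3, 7 and 14 after cardiotoxin (CTX), a cobra venom toxin that kills muscle fibres and is followed by regeneration. CTX was given into the muscle as 0.03 mL at 0.03 mg/mL. A further library held untreated cells of 5 groups, each marked with its own antibody hashtag: Dmdmdx mice, which lack dystrophin, at 2.5, 5 and 12.5 weeks, and DBA/2J mice at 2.5 and 12.5 weeks. The genome build was mm10 throughout, and gene positions below are on it.

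The uninjured library held 6602 cells and 16299136 unique molecular identifiers (UMIs), with a median of 2365 UMIs per cell. The day 0.5 library had 6927 cells and a median of 4593 UMIs, day 1 had 9941 cells and 6736 UMIs, and day 3 had 6130 cells and 11009.5 UMIs. Days 7 and 14 had 7449 and 7182 cells, with medians of 6478 and 5335.5 UMIs. In the hashed library the Dmdmdx groups had 2528, 3310 and 3074 cells by rising age, with medians of 7177.5, 10196 and 7020.5 UMIs. The DBA/2J groups had 2396 cells at 2.5 weeks and 2342 at 12.5 weeks, with medians of 7815.5 and 4920.5 UMIs. Total UMIs ran from 11910042 in DBA/2J at 12.5 weeks to 76616540 at day 1. There are no replicates: every group is 1 library or 1 hashtag, so no test between groups was made, and the 95% intervals of folds and shares cover counting error only. Expression is given as CPM, a gene's share of its group's summed UMIs on the usual scale.

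The first question was what stromal cells express within hours of muscle injury, at day 0.5 against the uninjured library. Genes for secreted signals that draw in leukocytes were far higher. Cxcl5, a neutrophil chemokine (chromosome 5, 90759360 to 90761624, plus strand), was at 3906 CPM against 0.736, a ratio of 5305 (3037 to 10270). Ccl2, the main monocyte chemokine (chromosome 11, 82035571 to 82037453, plus strand), was at 5226 CPM against 10.6, a ratio of 492 (424 to 575). Ptx3, a soluble pattern-recognition protein, was at 4353 CPM against 8.34, a ratio of 522 (441 to 622). Cxcl3 was at 323.5 CPM against a count of 0, at least 1757-fold higher when the uninjured library is set at a floor of 3 counts. All 9 measured members of the myeloid recruitment list were at least 2-fold higher, with a median log2 ratio of 6.81 that exceeded all matched random lists (percentile 100). That list and the early-responder markers follow what the series title names, so their direction is not independent evidence.

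Other gene groups differed at day 0.5 as well. In the NF-kB and IL-1 response list 11 of 16 genes were at least 2-fold higher and none was lower, with Il6 at 152 CPM against 1 count (ratio 2480, interval 445 to 97960) and Saa3, an acute-phase protein, at 257 CPM against 0.675. All 14 ribosome biogenesis genes were at least 2-fold higher, among them Myc at a ratio of 15.7 and Nop58 at 9.75. In glycolysis and hypoxia 7 of 12 genes were higher and 1 lower, with the lactate-forming enzyme gene Ldha at 6.53 and the glucose transporter gene Slc2a1 at 6.79. Of 7 provisional matrix genes, those of the early wound scaffold, 4 were higher and 1 was lower. They included the hyaluronan synthase gene Has1 at a ratio of 91.6 and Tnc, for tenascin C, at 76.0, a log2 ratio of 5.85 that was 6.68 with cells thinned to 1 depth and 6.49 with the mean of each cell's CPM. Tnc and Thbs1, for thrombospondin 1, led a day 0.5 cluster of 1696 cells with a median of 1872 UMIs, in which 2.95% of UMIs were mitochondrial against 0.796% to 1.65% in the other clusters. The alarmin gene Il33 was at 1125 CPM against 159. Only 8 of the 18 cell cycle genes reached 10 CPM. Of these 4 were higher and 1 lower, with a median of 1.09 and the replication gene Mcm5 at 17.2 CPM against 3.19 (log2 ratio 2.12, or 2.78 with cells thinned to 1 depth). None of the 7 proliferating markers reached that minimum, and the cell division gene Birc5 was at 2.21 CPM against 3.68. Complement had 6 of 8 genes at least 2-fold lower, with the inhibitor genes Cd55 at a ratio of 0.155 and Serping1 at 0.276 and a median of −1.68 (−1.07 with cells thinned to 1 depth), and the interferon response had 9 of 14 lower and 1 higher. Among single genes, Dact2, for an inhibitor of developmental signalling (chromosome 17, 14195052 to 14204304, minus strand), was at 1.05 CPM against 259. Cd34, a surface marker of quiescent stromal cells, was at 87.1 CPM against 1395. In all, 1269 of 6277 genes were at least 2-fold higher and 1324 lower, or 1713 and 990.0 with TMM factors, which turns the balance. The median log2 ratio of all these genes was 0.05 with totals as the scale and 0.29 with TMM factors.

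At day 1 the question was the same, and genes of DNA replication were higher along with the chemokine genes. Cxcl5 was at 4855 CPM (ratio 6594, interval 3775 to 12760), Cxcl1, another neutrophil chemokine, at 1987 CPM against 17.8, and Saa3 at 1047 CPM against 0.675. Csf3, the gene of the granulocyte growth factor G-CSF, was at 79.5 CPM against a count of 0, at least 432-fold higher. All 14 measured cell cycle genes were at least 2-fold higher, with the replication helicase gene Mcm5 at a ratio of 28.8 (21.9 to 38.5) and the mitotic kinase gene Cdk1 at 22.3 (15.7 to 32.9). Structural matrix genes were lower: 14 of 17 fibrillar matrix genes were at least 2-fold lower and 1 was higher, with Col1a1 at 563 CPM against 2668 and Col1a2 at 932 CPM against 4802, both chains of type I collagen. That list's median log2 ratio was −1.91, below all random lists, and 4 of 5 tendon markers were lower with it and 1 higher (median −2.40).

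In other lists at day 1, basement membrane had 7 of 9 genes lower, with a median of −1.58 (−1.05 with cells thinned to 1 depth), and complement 6 of 8, and the interferon response had 10 of 14 lower and 1 higher. Antigen presentation by class I molecules had 5 of 8 genes lower and 1 higher. All 14 ribosome biogenesis genes were at least 2-fold higher, as were 14 of 17 in the NF-kB and IL-1 response list. Myeloid recruitment had 8 of 10 genes higher, with a median log2 ratio of 6.53, or 7.32 with the genes at 0 set at their bound. Pi16, a marker of adventitial stromal cells (chromosome 17, 29317680 to 29330593, plus strand), was at 236 CPM against 6416, a log2 ratio of −4.76 that was −4.18 with the mean of each cell's CPM. The totals were 1166 of 6144 genes at least 2-fold higher and 1224 lower. With TMM factors these became 1894 and 800.0, as the median of all genes moved from 0.03 to 0.40. Percentages of cells over the 5% mitochondrial limit were 9.64 at day 0.5 and 10.1 at day 1, against 0.954 in the uninjured library.

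The title of the series names a discrete early-responder subtype, so the spread of these transcripts over cells was measured with every cell thinned to 1000 UMIs. Cxcl5 had a UMI in 64.2% of day 0.5 cells (63.1 to 65.4, Clopper-Pearson), 63.5% of day 1 cells (62.5 to 64.4), 15.3% of day 3 cells and 0.0812% of uninjured cells. Its share in cells of a type that should lack it was not measured. In the cluster with the lowest share, Cxcl5 had a UMI in 31.5% of cells at day 0.5 (median 2593 UMIs per cell) and in 28.4% at day 1 (median 4230 UMIs). In the cluster with the highest share, the values were 82.6% at day 0.5 (median 8745.5 UMIs) and 98.0% at day 1 (median 11045 UMIs). That day 1 cluster held 402 cells, 4.04% of its library, and was the only cluster named after the early-responder markers. Cxcl5, Cxcl1, Ccl2, Il6, Ptx3, Csf3 and Tnfaip6 were among its 30 leading genes. Counting the 8 early-responder markers together, 96.94% of day 0.5 cells and 95.51% of day 1 cells had at least 1 UMI. The 10% of cells with the most such UMIs held 30.68% of them at day 0.5 and 37.33% at day 1. An even spread over cells would give 14.08% and 14.63%. Free RNA in the droplets adds to the shares of cells and was not measured, since empty droplets are not in the deposited tables.

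**Figure D1:**
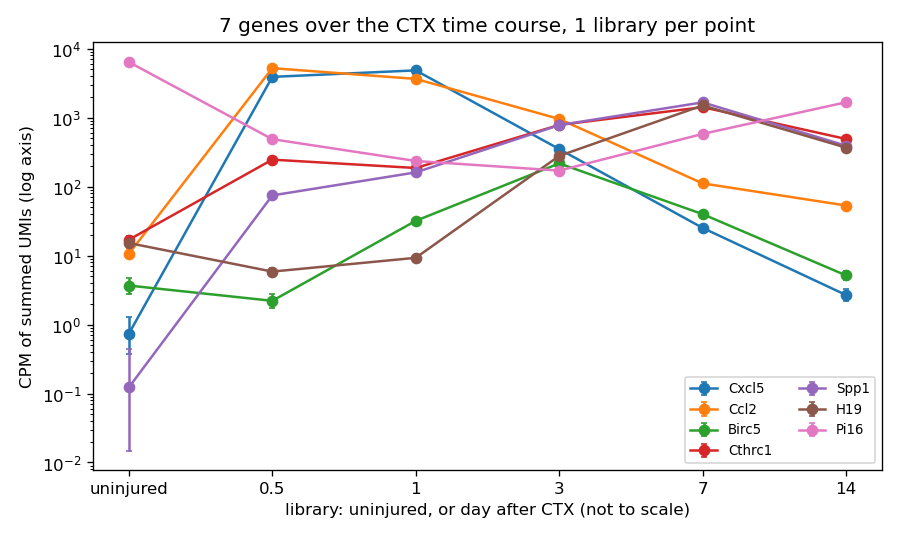
CPM of summed UMIs (log axis) for 7 genes in the uninjured library and at days 0.5, 1, 3, 7 and 14 after CTX, 1 library per point; bars are 95% counting intervals. Cxcl5 and Ccl2 were highest at day 1 (4855 CPM) and day 0.5 (5226 CPM), Birc5 at day 3 (217 CPM), and Cthrc1, Spp1 and H19 at day 7 (1421, 1668 and 1505 CPM), while Pi16 was highest in the uninjured library (6416 CPM).

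Day 3 asked what follows the first response, against the uninjured library. Genes of dividing cells and of contractile, matrix-building fibroblasts were higher. Birc5, needed for cell division, was at 217 CPM against 3.68, a ratio of 59.1 (45.9 to 77.4), and all 18 cell cycle genes were at least 2-fold higher, with a median log2 ratio of 3.95. Acta2, the smooth muscle actin of myofibroblasts, was at 459 CPM against 4.79, a ratio of 95.9 (76.8 to 121). Cthrc1, a secreted protein of activated fibroblasts (chromosome 15, 39076932 to 39087121, plus strand), was at 786 CPM against 17.0, and 9 of 10 myofibroblast genes were at least 2-fold higher. Spp1, the gene of osteopontin (chromosome 5, 104435118 to 104441050, plus strand), was at 781 CPM against 2 counts, a ratio of 6363 (1761 to 52540).

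Complement had all 8 genes lower at day 3, with a median log2 ratio of −2.07 and C3 at 239 CPM against 1275 (log2 ratio −2.41, or −3.11 in cells at or above their library's median UMI count). In the unfolded protein response 7 of 13 genes were higher, among them Calr, for an endoplasmic reticulum chaperone, at a ratio of 3.13. Glycolysis and hypoxia had 9 of 13 higher and 2 lower. Fibrillar matrix genes were mixed, with 2 of 17 higher and 2 lower. Bgn, for biglycan, was at a ratio of 4.36 and the collagen crosslinker gene Lox at 12.7, while the decorin gene Dcn was at 0.198. The median of that list, 0.05, changed sign among the settings tried. Gsn, for the actin-severing protein gelsolin, was at 1859 CPM against 43470, and Pi16 at 171 CPM against 6416, a log2 ratio of −5.22 that was −4.40 with cells thinned to 1 depth, −4.38 with the mean of each cell's CPM and −6.89 among cells at or above their library's median UMI count. Gsn went from −4.55 to −3.95 with that mean and −5.43 in those deeper cells. Thinned to 1000 UMIs, 8.73% of day 3 cells and 69.3% of uninjured cells had a Pi16 UMI, and the lowest cluster shares were 0 at day 3 (median 1346 UMIs) and 24.1% in the uninjured library (median 2466 UMIs). In all, 999 of 6205 genes were at least 2-fold higher and 731 lower.

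Days 7 and 14 asked which differences from uninjured cells are found late in regeneration. Most fibrillar matrix genes were higher on both days, while basement membrane genes had 2 of 9 higher and 1 lower on day 7 and none past 2-fold on day 14. Col1a1 was at 12910 CPM on day 7 and 11070 on day 14 against 2668, ratios of 4.84 and 4.15, and 10 and 11 of the 17 fibrillar matrix genes were at least 2-fold higher, with 1 lower on day 7. Tendon markers were higher with them, 7 of 8 on day 7 and 6 of 6 on day 14 (medians 3.00 and 2.15). All 10 measured myofibroblast genes were higher on day 7 and all 9 on day 14, with median log2 ratios of 4.65 and 2.12. Spp1 was at 1668 CPM on day 7 and 392 on day 14 against 2 counts, ratios of 13600 (3764 to 112300) and 3195 (884 to 26390). The day 14 log2 ratio of 8.45 was 7.82 with cells thinned to 1 depth and 7.69 with the mean of each cell's CPM. Imprinted genes of fetal growth had some of the highest ratios. H19, a maternally expressed long noncoding RNA (chromosome 7, 142575529 to 142578143, minus strand), was at 1505 CPM on day 7 and 368 on day 14 against 15.2, ratios of 98.9 (87.3 to 113) and 24.2 (21.3 to 27.5).

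Dlk1, a paternally expressed inhibitor of adipocyte formation (chromosome 12, 109452823 to 109463336, plus strand), was at 323 CPM on day 14 against 6.50, a ratio of 49.6 (41.0 to 60.7) whose log2 value of 5.43 was 4.75 without clusters led by other cell types' markers, and Mest, another imprinted gene, at 343 CPM against 19.3. In the interferon response 11 of 17 genes were at least 2-fold higher on day 7 and 9 of 16 on day 14. Cell cycle genes were higher in 14 of 17 cases on day 7 and in 0 of 5 on day 14. Complement had 3 of 8 lower on day 7. Matrix proteases had 7 of 11 higher and 2 lower on day 7 and 7 of 10 higher and 1 lower on day 14, with the collagenase gene Mmp13 at 68.1 CPM on day 7 against 1 count (ratio 1110, interval 199 to 43870). Of the 10 stromal growth factor genes, 4 were higher on day 14, among them Igf1 at a ratio of 3.67 and Gas6 at 3.07. The eosinophil chemokine gene Ccl11 was at 373 CPM on day 14 against 27.4. Thinned cells had an H19 UMI in 51.7% of cases on day 7 and 16.0% on day 14. H19 shares by cluster ran from 9.48% (median 8793 UMIs) to 66.6% (median 3501 UMIs) on day 7, and from 4.62% (5108 UMIs) to 42.1% (6108 UMIs) on day 14, where the cluster with the highest share is the 1 of 313 cells led by muscle fibre markers. Spp1 ran from 3.59% (5985 UMIs) to 44.8% (8058 UMIs) on day 7. Totals were 654 of 6202 genes higher and 383 lower on day 7, and 398 of 5975 higher and 223 lower on day 14.

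**Figure D2:**
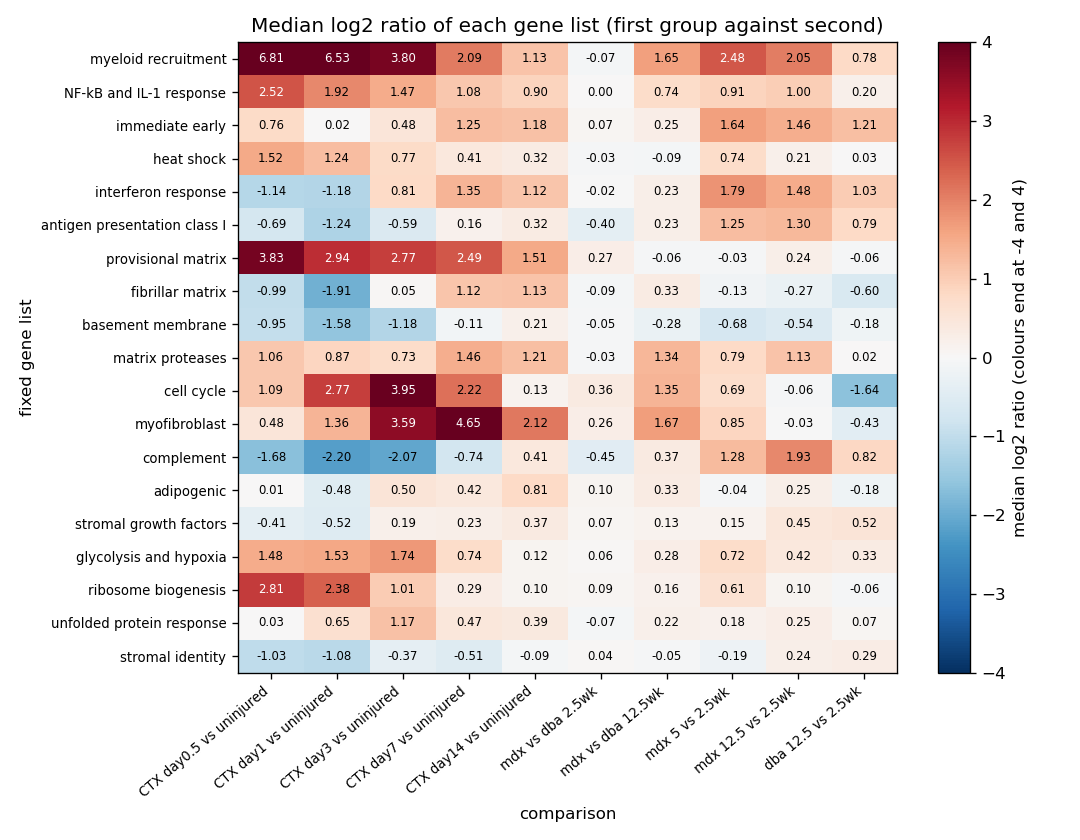
Median log2 ratio (colour, ends at −4 and 4, with the value printed) of 19 gene lists down the side in 10 comparisons along the bottom. Myeloid recruitment was at 6.81 at day 0.5 and 6.53 at day 1 (7.32 with genes at 0 set at their bound), cell cycle was highest at day 3 (3.95) and myofibroblast at day 7 (4.65); medians near 0 changed sign under some settings.

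Markers of other cell types were summed over each library of the injury course. Ptprc, the pan-leukocyte gene, reached 2.58 CPM, and Lyz2, abundant in macrophages, 27.7 CPM at day 7, while the T cell gene Trbc2 was at 30.4 CPM in the uninjured library. The neutrophil gene S100a8 reached 5.47 CPM at day 1, the endothelial gene Egfl7 9.87 CPM at day 3 and the myoblast gene Myog 4.2 CPM at day 7. Acta1, the actin of muscle fibres, was at 26.1 CPM in the uninjured library, 0.421 at day 0.5, 52.6 at day 7 and 45.4 at day 14. At day 3 all 4 measured muscle fibre markers were at least 2-fold lower (median −3.25), while H19 was at 279 CPM against 15.2. The haemoglobin gene Hbb-bs was at 53.9 CPM in the uninjured library and 1.19 at day 1. Tendon cell markers were higher at days 7 and 14, with Tnmd at 478 CPM against 49.5 at day 7. A day 3 cluster of 108 cells (median 15631.5 UMIs) had the T cell genes Cd3d, Cd3g and Trbc2, Lyz2 and haemoglobin genes among its leading genes, with stromal genes at 0.722 of their level elsewhere. A day 14 cluster of 313 cells had 6 muscle fibre markers among its leading genes, with stromal genes at 0.914. Larger clusters had such genes too. A day 7 cluster of 2417 cells had haemoglobin genes and muscle fibre markers among its leading genes, with stromal genes at 1.21. An uninjured cluster of 1783 cells had haemoglobin genes among them, with stromal genes at 0.906. Of perineurial, pericyte and adipocyte genes, Lypd2 reached 5.71 CPM, Cspg4 10.4 and Adipoq 3.36.

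Dmdmdx against DBA/2J at 2.5 weeks asked whether stromal cells differ near the start of the dystrophy. Few genes did: 8 of 6082 were at least 2-fold higher and 6 lower. These counts were 11 and 3 with cells thinned to 1 depth, and 16 and 17 in cells at or above their group's median UMI count. Dlk1 was at 1029 CPM against 244, a ratio of 4.22 (4.09 to 4.36). Igf2, an imprinted fetal growth factor (chromosome 7, 142650766 to 142666816, minus strand), was at 1300 CPM against 570.3, a ratio of 2.28 (2.23 to 2.33), and the neighbouring H19 at 1544 CPM against 772, a ratio of 2.00. Mmp3, for stromelysin, a matrix protease (chromosome 9, 7445822 to 7455975, plus strand), was lower, at 108 CPM against 223. Of 13 imprinted genes 3 were at least 2-fold higher. Muscle fibre markers had a median log2 ratio of 0.57, but only 1 of 7 passed 2-fold, the troponin gene Tnnc2 at 67.1 CPM against 31.1. Red cell markers had a median of 0.63 over 3 genes, with none at 2-fold. The fat cell genes Fabp4 and Adipoq were at 63.7 against 14.7 CPM and 6.15 against 0.263 CPM. Without cells over 5% mitochondrial UMIs the log2 ratio of Fabp4 was 0.29 in place of 2.04, and with the mean of each cell's CPM it was 1.31.

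By list at 2.5 weeks, none of 8 complement genes and none of 7 class I antigen presentation genes reached 2-fold, with medians of −0.45 and −0.40 log2, both below all random lists. Among 11 cell cycle genes the median was 0.36, above all random lists, with none at 2-fold. The age labels are equal, but the hashtag names in the deposited metadata read 18 days for Dmdmdx and 15 days for DBA/2J, and 86 and 91 days at 12.5 weeks. Thinned to 3000 UMIs, 59.0% of Dmdmdx and 30.3% of DBA/2J cells had a Dlk1 UMI. The lowest cluster had 21.7% (median 7875 UMIs) in Dmdmdx and 6.11% (8446 UMIs) in DBA/2J. Dmd itself, the dystrophin gene (chromosome X, 82948870 to 85206141, plus strand), was at 23.6 CPM in Dmdmdx and 27.3 in DBA/2J.

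At 12.5 weeks the same comparison asked how stromal cells differ in established dystrophy, and 130.0 of 6233 genes were at least 2-fold higher and 135 lower, or 163 and 106 with TMM factors. Spp1 was at 432 CPM against 25.2, a ratio of 17.1 (15.3 to 19.3) whose log2 value of 4.05 was 3.45 with cells thinned to 1 depth, 3.40 with the mean of each cell's CPM and 4.73 in the deeper cells, those at or above their group's median UMI count. Mmp3 was at 803 CPM against 117, a ratio of 6.89 (6.52 to 7.28), and Ccl2 at 410 CPM against 82.1, a ratio of 4.99 (4.67 to 5.33). Postn, for the matrix protein periostin, was at 1291 CPM against 331, a ratio of 3.90 (3.77 to 4.03). Lower genes included Hsd11b1, for an enzyme that activates glucocorticoids, at 50.6 CPM against 257, Inmt, for a methyltransferase, at 85.6 against 356, and Nr1d1, for a repressor of the circadian clock (chromosome 11, 98767932 to 98775333, minus strand), at 20.03 CPM against 107, a ratio of 0.187 (0.168 to 0.208).

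Myeloid recruitment at 12.5 weeks had 4 of 7 genes higher and 1 lower, with Ccl7, another monocyte chemokine, at a ratio of 6.27 and Cxcl5 at 6.89. Matrix proteases had 6 of 11 higher, myofibroblast genes 5 of 9, and cell cycle genes 9 of 13, with Top2a at 15.7 CPM against 1.93. Complement had 2 of 8 higher, with C4b at a ratio of 3.61, and fibrillar matrix 2 of 17, with Col1a1 at 2.23. Muscle fibre and red cell transcripts were lower with them: Acta1 at 24.3 CPM against 103, and Hbb-bs at 311 against 858. Of thinned cells, 50.8% in Dmdmdx and 16.5% in DBA/2J had an Mmp3 UMI, with lowest cluster shares of 24.1% (median 6112.5 UMIs) and 13.8% (4676 UMIs). For Spp1 the shares were 7.04% (6.15 to 8.01) and 5.61% (4.67 to 6.66), which overlap. They lie close to the lowest cluster shares of 4.31% (median 6940.5 UMIs) and 4.44% (5541.5 UMIs), so most Spp1 shares cannot be set apart from background, while 20.5% of cells in the highest Dmdmdx cluster (9354.5 UMIs) had a UMI. In the deeper cells 215 genes were lower, and without clusters taken by the looser rule, which held 1396 of the 2342 DBA/2J cells, 238 were. A pool cluster of 1707 cells taken by that rule was led by Hsd11b1 and had Cxcl14 stromal markers beside haemoglobin genes. Its stromal genes were at 0.805 of their level elsewhere. Another pool cluster, of 625 cells, had Cxcl5, Ccl2, Ccl7, Ptx3 and all proliferating markers among its leading genes. Its median of 14318 UMIs was the highest of the pool clusters, and its stromal genes were at 0.451. The chemokine and cell cycle differences may thus come in part from the same cells, which was not tested. With cells thinned to 1 depth the myofibroblast and cell cycle medians were 0.92 and 0.70 in place of 1.67 and 1.35, and the log2 ratios of Ccl2, Cxcl5, Ccl7 and Top2a were 1.49, 1.29, 1.94 and 1.53 in place of 2.30, 2.60, 2.61 and 2.51. With the mean of each cell's CPM these 4 were 1.43, 1.63, 1.73 and 1.30, and in the deeper cells Cxcl5 and Top2a were at 3.19 and 3.40. Under the rule that left out clusters, Hsd11b1 was at −1.09 in place of −2.32 and Inmt at −2.65 in place of −2.04, and Inmt was at −2.93 in the deeper cells.

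**Figure D3:**
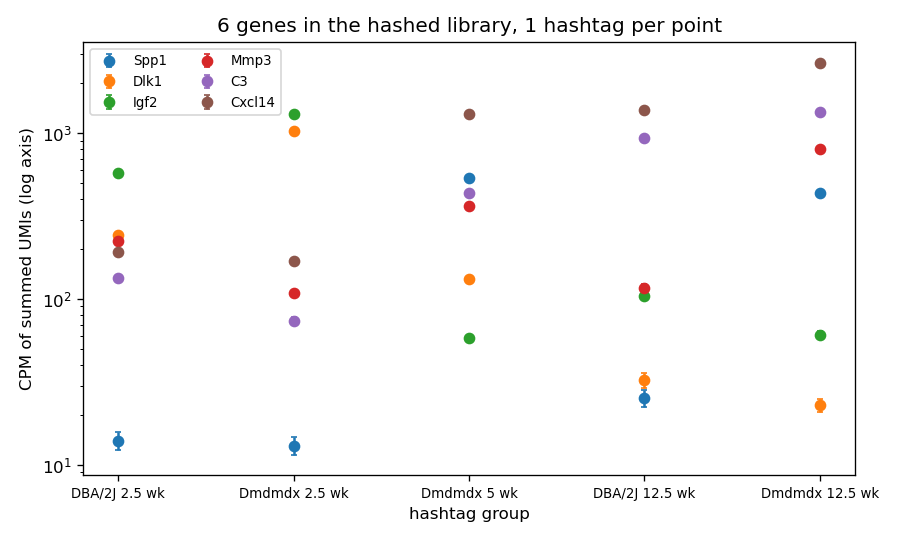
CPM of summed UMIs (log axis) for 6 genes in the 5 hashtag groups, 1 hashtag per point, with 95% counting intervals as bars. Spp1 was at 13.0 to 25.2 CPM in Dmdmdx at 2.5 weeks and both DBA/2J groups and at 538 and 432 CPM in Dmdmdx at 5 and 12.5 weeks; Igf2 and Dlk1 were highest in Dmdmdx at 2.5 weeks (1300 and 1029 CPM).

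Within Dmdmdx, 5 weeks against 2.5 weeks asked what differs by the age of the first wave of fibre death. There was no DBA/2J group at 5 weeks, so growth with age and dystrophy cannot be told apart in this comparison. Spp1 was at 538 CPM against 13.0, a ratio of 41.4 (36.5 to 47.2) whose log2 value of 5.27 was 5.87 in the deeper cells, Cxcl5 at 165 CPM against 6.26, a ratio of 26.4 (22.0 to 32.0), and Ccl2 at 639 CPM against 48.0, a ratio of 13.3 (12.4 to 14.2). With cells thinned to 1 depth, Cxcl5 and Ccl2 had log2 ratios of 3.52 and 3.00 in place of 4.52 and 3.71, and with the mean of each cell's CPM 3.68 and 2.93, while Cxcl5 was at 5.13 without the 5% of cells with the highest doublet scores. Tnc was at 158 CPM against 10.95, and Thbs4, for a thrombospondin of tendon and muscle matrix, at 1387 CPM against 114. Igf2 was at 57.8 CPM against 1300, a ratio of 0.0445, and Dlk1 at 132 against 1029. Muscle fibre markers moved with these imprinted genes: all 7 measured were at least 2-fold lower, with a median log2 ratio of −2.62. The interferon response had 12 of 14 genes at least 2-fold higher and 1 lower, class I antigen presentation 6 of 8 and immediate early genes 10 of 14, a group that tissue digestion can also induce. Complement had 4 of 8 higher and 1 lower. Basement membrane had 4 of 9 lower, and pericyte or smooth muscle markers 2 of 4 (median −0.81). Counting all genes, 304 of 6422 were higher and 273 lower. The 10% of cells richest in early-responder transcripts held 75.38% of them at 5 weeks and 51.12% at 2.5 weeks, with 21.26% and 33.32% under an even spread. Ccl2 had a UMI in 14.7% of thinned cells at 5 weeks (5.63% in the lowest cluster, median 9967.5 UMIs, and 69.5% in the highest, 19500 UMIs).

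At 12.5 against 2.5 weeks within Dmdmdx, complement genes stood out, with 7 of 8 at least 2-fold higher. The central component C3 was at 1341 CPM against 73.7, a ratio of 18.2 (17.2 to 19.2), and C4b at 741 against 36.2, a ratio of 20.5 (18.9 to 22.1). Cxcl14, a chemokine of a resident stromal subset, was at 2654 CPM against 169. Spp1 had a ratio of 33.2 (29.2 to 37.9), a log2 ratio of 4.95 that was 4.08 with cells thinned to 1 depth, 4.23 with the mean of each cell's CPM and 5.73 in the deeper cells. Dlk1 was at 22.8 CPM against 1029 and H19 at 99.5 against 1544, and all 7 muscle fibre markers were likewise at least 2-fold lower (median −2.43). Myeloid recruitment had 5 of 7 higher, class I antigen presentation 6 of 8, the interferon response 9 of 13 and immediate early genes 10 of 14. The totals were 272 of 6292 genes higher and 197 lower.

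The same ages were compared in DBA/2J, the strain without the mutation, to see what differs with age there. Inmt was at 356 CPM against 15.8, a ratio of 22.5 (20.04 to 25.4), Prg4, for the joint lubricant lubricin, at 862 CPM against 92.6, and C3 at 934 against 134. Collagen genes were lower, with Col1a1 at 3280 CPM against 15170 and Col3a1 at a ratio of 0.317 (0.315 to 0.319), and 7 of 17 fibrillar matrix genes were at least 2-fold lower and 1 was higher. Pericyte or smooth muscle markers were lower in 3 of 4 cases (median −1.84), while tendon markers were higher in 3 of 5 (median 1.06). Cell cycle genes were lower in 8 of 11 cases. Dlk1 was at 32.3 CPM against 244, and Peg3, another imprinted gene, at 82.5 against 638, with 2 of 6 muscle fibre markers at least 2-fold lower (median −0.47). Immediate early genes were higher in 9 of 13 cases, the interferon response in 6 of 12 and complement in 3 of 8. Clusters taken by the looser rule held 1396 of the 2342 cells at 12.5 weeks. Without them the log2 ratios of the immediate early genes Fos and Btg2 were 0.80 and 0.96 in place of 1.52 and 1.71, under 2-fold. With cells thinned to 1 depth the cell cycle gene Ube2c was at −0.84 in place of −1.93, and it was at −2.58 in the deeper cells. Red cell transcripts moved as well, with Hbb-bs at 858 CPM against 269. In all, 206 of 6295 genes were higher and 155 lower.

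Setting the injury course beside the hashed groups asked whether dystrophic and injured stromal cells share differences. Within each of the 25 pairs the comparisons use no library in common, but all pairs share the uninjured library and the hashed pool. Each Spearman correlation is across genes, which are not independent replicates. Dmdmdx against DBA/2J at 12.5 weeks had a correlation of 0.617 with day 7, where 169 of the 173 genes at least 2-fold different in both went the same way, and of 0.580 with day 3. For 5 against 2.5 weeks in Dmdmdx, which has no DBA/2J counterpart, it was 0.639 with day 3, with 339 of 355 genes the same way. For 12.5 against 2.5 weeks in Dmdmdx it was 0.124 with day 7, with 149 of 220 genes the same way, and at most 0.232 with any day. For DBA/2J age it was −0.373 with day 7, and for the strains at 2.5 weeks it was at most 0.066. DBA/2J at 12.5 weeks is the reference in the strain comparison at that age and the first group in DBA/2J age. Opposite signs of those correlations are therefore not independent. Depth was not matched here, and every injured library had a higher median UMI count than the uninjured library (2365). Medians were likewise higher in Dmdmdx than DBA/2J at 12.5 weeks (7020.5 against 4920.5) and in Dmdmdx at 5 than 2.5 weeks (10196 against 7177.5). In DBA/2J they were lower at 12.5 than 2.5 weeks (4920.5 against 7815.5). Depth and shared biology therefore cannot be told apart in these correlations.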

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

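The neutrophil, age gap and circadian tests below were chosen after the results they measure had been seen, as were the imprinted and clock gene lists; the limits of the depth, damaged cell and muscle fibre RNA tests were written before those test values were computed, but with the patterns already seen. The choice of deeper cells in the damaged cell test was made after seeing the data, and that the intervals must also pass the muscle fibre limits was decided after its values had been seen.

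A gene was singled out here when it differed by at least 2-fold in opposite ways in both contrasts, with at least 50 CPM in 1 of the groups each time, and a list when its medians had opposite signs and both lay in the outer 2.5% of the random lists at either end. For Dmdmdx against DBA/2J at the 2 ages this took 1 gene and 4 lists, while other genes and lists with opposite signs did not meet it, and these differences between ages were not tested, since each group is 1 hashtag. Mmp3 had a log2 ratio of −1.03 at 2.5 weeks and 2.77 at 12.5 weeks, a difference of −3.81. Complement had medians of −0.45 and 0.37, a difference of −0.82, and class I antigen presentation −0.40 and 0.23, a difference of −0.62. Fibrillar matrix had −0.09 and 0.33, a difference of −0.42, and the unfolded protein response −0.07 and 0.22, a difference of −0.28. By age, the complement gene C2 was higher at 12.5 weeks in Dmdmdx (1.58) and lower in DBA/2J (−1.02), a difference of 2.60 that was not tested either.

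Chemokine genes were far higher at days 0.5 and 1 after CTX than in the uninjured library, whose cells were sequenced less deeply. With all cells thinned to 1 depth the median of the recruitment list was 1.01 and 0.978 of its full value at the 2 days. Thinning at random keeps each cell's expected proportions, so a value near 1 was likely in advance and cannot exclude the depth gap. Among cells at or above their library's median UMI count the median of that list was 0.976 and 1.02 of its full value, which argues against damaged cells of low count as the source. The neutrophil transcripts S100a8 and S100a9 together were at 0.0128 and 0.0155 of the level of Cxcl2 plus Cxcl3, far below what RNA of infiltrating neutrophils would bring. Expression by the stromal cells themselves is a hypothesis that these tests leave standing, and cell digestion, which was the same for every library by the labels, was not tested.

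Most imprinted genes of a list chosen for this pattern, and so not set against random lists, were at least 2-fold higher at days 7 and 14, 11 of 13 and 8 of 12 (median log2 ratios 2.35 and 2.04), though Sgce and Ndn were slightly lower. In Dmdmdx against DBA/2J at 2.5 weeks 3 of 13 were (median 0.52), among them Dlk1 and Igf2. Muscle fibre markers had medians of 0.94, 0.77 and 0.57 in these comparisons, and red cell markers −0.17, −0.72 and 0.63. If both came as free RNA from fibres, imprinted and fibre UMIs would keep 1 ratio in every cluster of a library. The highest ratio over the lowest was 2.51 (2.04 to 3.09) at day 14, 3.76 (3.01 to 4.69) at day 7 and 3.23 (2.92 to 3.57) in Dmdmdx at 2.5 weeks with counting error only, where at most 1.5 had been set as the sign of free RNA and at least 3 on both days as the sign against it. Day 7 passes the upper bound and day 14 does not, and the interval in Dmdmdx spans it, and on day 14 the cluster with the highest H19 share (42.1%) is itself led by muscle fibre markers. At day 3, outside this pattern, H19 was at 279 CPM against 15.2 while all 4 fibre markers were lower (median −3.25). This goes against RNA of fibres that carry these markers as the source of H19 on that day. RNA of muscle cells without these markers was not tested, and days 7 and 14 stay unsettled. Over the clusters measured, imprinted UMIs were 58.6 to 220 times the fibre marker UMIs at day 7 and 36.5 to 91.5 times at day 14. In Dmdmdx at 2.5 weeks they were 16.3 to 52.7 times. Meg3 was the most abundant imprinted gene in each, at 5353, 3676 and 3709 CPM, and was at 1655 CPM in the uninjured library. The ratios therefore weigh Meg3 most and say less about H19, Dlk1, Mest or Igf2. Their intervals also leave out that the highest and lowest clusters were picked. The ratio in fibres themselves was not measured, so the size of these values was not tested. For days 7 and 14 and for Dmdmdx at 2.5 weeks, free RNA and expression by the cells cannot be told apart here, and injury and strain stay open as biological sources. An age gap of 18 against 15 days at 2.5 weeks would need these genes to be higher with age, while in DBA/2J their median was −2.13 at 12.5 against 2.5 weeks. That contrast runs from 15 to 91 days by the hashtag names. It cannot give the direction between days 15 and 18, so the age gap is not excluded.

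Clock genes differed between the strains at 12.5 weeks: the 8 genes that peak with Dbp had a median of −1.55, with Nr1d1 at −2.36 and Dbp at −1.94. A different time of day at harvest would move the genes of opposite phase the other way. The 5 genes that peak with Arntl had a median of 0.16, so the difference between the gene sets was −1.71, nearly all of it from the first set, in which Per1 and Bhlhe41 were at 0.18 and 0.07. Between 12.5 and 2.5 weeks in Dmdmdx the sets went opposite ways, with medians of −1.56 and 0.82, as harvest at another time of day would bring, and in DBA/2J they were −0.07 and 0.58. In the other comparisons the medians had the same sign or at least 1 of them lay near 0. At 5 against 2.5 weeks in Dmdmdx they were −1.17 and 0.04, and between the strains at 2.5 weeks 0.26 and −0.13. Against the uninjured library both sets were lower at day 0.5 (−1.625 and −0.201), day 1 (−1.01 and −0.645) and day 3 (−1.161 and −0.669). Harvest time and a biological difference in the clock cannot be told apart, because the labels give no harvest times and Arntl itself was at −0.09.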

How the results depend on the processing

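Leaving out cells over 5% mitochondrial UMIs, the 5% with the highest doublet scores, the shallower cells of each group, and clusters led by other cell types' markers (the looser rule) were chosen after seeing the data. Of 20 counts of genes, all stayed within 1.5 times their value with the mean of each cell's CPM, without cells over 5% mitochondrial UMIs and without the highest doublet scores. The planned limit of 10% mitochondrial UMIs removed no cell and the planned rule for non-stromal clusters and doublets removed 10 cells, so neither says anything about stability. List medians lay within their counting intervals in 99 of 190 cases with TMM factors, 90 with thinned cells and 78 under the looser rule. No named gene past 2-fold changed direction under these settings, but some no longer reached 2-fold, among them Fabp4 between the strains at 2.5 weeks without cells over 5% mitochondrial UMIs (0.29) and Acta2 at 12.5 weeks with thinned cells (0.92).

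A lower gene minimum tests more genes and a higher one fewer, which by construction moves the counts. At 5 CPM, 1701 genes were higher and 2328 lower at day 0.5 and 1604 and 2160 at day 1; 1540 were higher and 1279 lower at day 3, 1183 and 662 at day 7, and 713 and 381 at day 14. For Dmdmdx against DBA/2J they were 14 and 14 at 2.5 weeks and 276 and 256 at 12.5 weeks. By age they were 497 and 488 for Dmdmdx at 5 weeks, 447 and 384 at 12.5 weeks, and 339 and 326 for DBA/2J. At 100 CPM, 533 were higher and 419 lower at day 0.5, 468 and 394 at day 1, 393 and 249 at day 3, 237 and 152 at day 7, and 153 and 80 at day 14. Between the strains they were 3 and 1 at 2.5 weeks and 51 and 47 at 12.5 weeks. By age they were 99 and 97, 103 and 61, and 67 and 61 in the same order.

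With TMM factors 1894 genes were higher and 800 lower at day 1, where the median of all genes moved to 0.40. Between the strains at 2.5 weeks, 3 genes were lower with thinned cells, and 16 were higher and 17 lower in the deeper cells. At 12.5 weeks 215 were lower in the deeper cells and 238 under the looser rule. The cause was not tested. At that age 4 list medians reversed: ribosome biogenesis to −0.019 with the mean of each cell's CPM, and, under the looser rule, interferon response to −0.009, basement membrane to 0.49 and glycolysis and hypoxia to −0.019. The cause was not tested, though that rule removed 1396 of the 2342 DBA/2J cells. Medians near 0 also changed sign, among them fibrillar matrix at day 3 and basement membrane at days 7 and 14.

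At 0.5 of the thinning depth the richest 10% of cells held 31.04% of early-responder UMIs at day 0.5 and 37.6% at day 1. Shares of cells depend on depth: 2721 moved beyond their interval at that depth and 193 did not. Clusters at day 1 had an adjusted Rand index of 0.538 with another seed and 0.324 at resolution 0.3, so cluster shares there depend on the clustering. In the uninjured library 0, 1 or 2 counts stand behind several of the ratios given, so their size is poorly known.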

Other observations

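The imprinted list used in this part was chosen after its values had been seen. Stromal subsets differed in their markers over the injury course. Dpp4 stromal markers, of an adventitial subset, had a median log2 ratio of −2.66 at day 0.5, −3.08 at day 1, −2.62 at day 3, −2.42 at day 7 and −1.60 at day 14, with 5 of 8 still at least 2-fold lower at day 14. Cxcl14 stromal markers, of a resident subset of the muscle interstitium, had medians of −1.35, −1.55, −1.28, −0.25 and 0.38, although Cxcl14 itself was at 3950 CPM at day 0.5 against 716 in the uninjured library. Matrix-remodelling markers had medians of 3.78, 2.31, 4.45, 5.23 and 3.09, and interferon-responsive markers −1.02, −1.10, 1.07, 1.61 and 1.77. Proliferating markers had medians of 2.73 at day 1, 4.97 at day 3 and 2.93 at day 7. Tendon markers were at −1.82, −2.40, 0.28, 3.00 and 2.15 over the 5 days, with Scx, a tendon transcription factor, at 56.6 CPM against 1.35 at day 7.

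Other lists were less uniform. Stromal identity genes, surface markers of stromal cells, had 3 of 6 members lower at days 0.5 and 1, with medians of −1.03 and −1.08, the latter −0.71 with TMM factors. Heat shock genes had 5 of 8 higher and 1 lower at day 0.5, with the mitochondrial chaperone gene Hspd1 at a ratio of 7.30. Immediate early genes had 5 of 14 higher and 3 lower at day 0.5 and 8 higher and 1 lower at day 7. Adipogenic genes had a median of 0.81 over 4 members at day 14, with 1 at least 2-fold higher, and 0.51 under the looser rule for leaving out clusters. In dystrophic muscle at 12.5 weeks, Dpp4 stromal markers had a median of −0.84 against DBA/2J, and 6 of 7 matrix-remodelling markers were at least 2-fold higher. At 5 against 2.5 weeks in Dmdmdx, tendon markers were at 1.60 and Dpp4 stromal markers at −2.11, with all 8 at least 2-fold lower.

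Of imprinted genes 10 of 11 were at least 2-fold lower at day 0.5 and 9 of 10 at day 1 (medians −1.98 and −1.82), while Dlk1 was at 0.89 at day 0.5. Markers of other cell types were lower with them: muscle fibre markers at medians of −3.35 and −3.36, 4 of 4 on both days, and red cell markers at −2.64 and −4.17, 3 of 3. At day 3 the imprinted median was 0.55, with 3 of 11 higher and 2 lower. The imprinted list was not set against random lists. Median mitochondrial shares were 3.54% to 4.02% in the hashed groups and 0.765% to 1.25% in the CTX libraries. Dmd was at 12.9 CPM in the uninjured library and 1.13 at day 0.5.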
